A study of Mus musculus with 18 samples.

How the data were processed

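Whole islets isolated from 5-week-old mice on normal chow were profiled by RNA-seq in 4 groups set by sex and by MafA genotype, wild type or heterozygous for S64F. Per the labels' protocols, RNA was extracted with a column kit, only samples with an RNA integrity number above 8.0 were used, and libraries were sequenced paired-end with 150-nucleotide reads on an Illumina NovaSeq6000. Groups and replicate numbers came from the sample titles, and table columns were matched by name.

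The deposited tables hold a raw count per gene and library, 1 column per library, made by the authors from reads on GRCm38. The submitters' processing notes name STAR, featureCounts, FastQC, MultiQC and DESeq2 with no version or role. The annotation, strand setting, trimming and handling of reads with several matches are not given in the sources used here. The authors also deposited FPKM values, which for all 33562 genes with a count equalled the count divided by the column total and by 1 whole-number length per gene (within 0.001 base). The FPKM values were therefore not tested. The tables list 53900 features, of which 99 are spike-ins with 0 counts in all libraries and were left out. The other 53801 are mouse genes. Gene coordinates and biotypes came from GENCODE M21 on the same build, in which 53706 gene identifiers were found and 95 were not. Genes were handled by identifier.

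Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the group as factor (minimum count 10, minimum total 15), which left 18364. Libraries were scaled by trimmed mean of M values (TMM), and 1 quasi-likelihood model with robust estimation and 1 coefficient per group was fitted to all 18 libraries. The biological coefficient of variation was 22.5%. Contrasts were S64F/+ against WT in males and in females, the male minus the female genotype effect (the interaction), and male against female within each genotype. P-values were adjusted by Benjamini-Hochberg within each contrast, two-sided, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and the check of the Y-linked genes uses the plain totals. Where a group held 0 counts of a gene, the fold was a lower bound against 3 counts over the group, and with 1 to 3 counts a ratio with an exact 95% interval was given. With 19.3 M counts in the smallest library, 3 counts over the male WT group correspond to 0.0259 CPM.

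Gene lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, for lists with at least 4 tested members, and again with the correlation estimated per list and with fry. The 29 lists, each named with its result, covered beta-cell function, ageing and stress, metabolism and growth, and markers of the other cells that islet preparations can hold. For 10 cell types the mean log2 CPM of the markers was compared by an exact permutation test of the libraries, two-sided, a comparison added after the main test had been seen. A list of 22 genes of alternatively activated macrophages was written after the main test had been seen.

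Genes were named by a fixed rule. It took Mafa, and for each genotype contrast and the interaction the 6 largest rises and the 6 largest falls among called genes with a mean of at least 1 CPM. In the genotype contrasts the ranges of the groups also had to be apart, and provisional symbols and pseudogenes were passed over. It took up to 2 called members per list with the smallest p, and in the sex contrasts Xist, Ddx3y, Eif2s3y, Kdm5d, Uty and the 4 largest rises and falls outside X and Y. Ins1, Ins2, Gcg, Sst, Cdkn1a and Cdkn2a were named whatever their p. Genes outside the rule, which are mostly the members listed where 5 or fewer were called and Aldh1a3, Retnla in males and the complement genes, were chosen after their values were seen. Some genes that the rule took are not reported here, although the counts of named results include them. The groups, designs, gene lists, naming rule and the alternatives listed below as planned were set before the data were examined.

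Counts of genes with near-identical copies are uncertain, since reads can be split between copies. This applies to Ins1 and Ins2, Rnase2a, Chil4, H2-M2, Xlr4a, Serpina1d, Reg1 and the acinar protease families. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart.

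The chi-square per degree of freedom between replicate counts was at least 20.4, so none was a repeat of another. Replicate numbers recur across groups. Deviations from the group means of same-numbered WT and S64F/+ libraries correlated at 0.110 to 0.418 in all 5 female pairs, which met the fixed criterion of 0.1, the lowest only just. The female numbers were thus taken as pairs, from the data and not from the labels. Pairs entered only the replicate block, the blocked test of oxidative phosphorylation genes and the splits that part them. The main gene and list tests and the permutation tests of marker levels hold no pair term. Female libraries of different numbers had -0.389 to 0.494. Libraries 4 and 5 went together (0.248 to 0.494, the highest being WT 4 with S64F/+ 5) and mostly against 1 to 3 (-0.389 to 0.016), so this structure does not follow the numbers alone. The male numbers did not meet the criterion.

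The tests were also run on counts simulated from the real means and library sizes, with 200 genes changed 1.5, 2 or 4-fold. Of these, 34.3%, 68.2% and 90.8% were called in males (18039 genes) and 47.7%, 70.3% and 84.4% in females (18056). In the interaction 17.9%, 63.6% and 81.5% were called (18039). False calls were 2.9% to 4.6% of calls, which need not hold for correlated genes or pairs.

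The alternatives planned were RLE factors, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared, a replicate block, the acinar marker level as a covariate, limma-voom with sample quality weights, and leaving out each library in turn. Scaling by library size alone and leaving out 2 pairs of libraries were added after seeing the data. Splits of the libraries into groups of the same sizes were refitted, all 35 for the male contrast and 60 drawn for each of the others. For the interaction the residuals of an additive model of sex and genotype on log2 CPM were also permuted over the 18 libraries and tested with limma (trend, robust) and camera, 100 permutations with the real order included, a test added after seeing the data.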

Results

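RNA-seq libraries were made from whole islets of Langerhans, the hormone-secreting cell clusters of the pancreas, isolated from 5-week-old mice on normal chow. The mice were wild type (WT) or heterozygous for MafA S64F (S64F/+), a single amino acid change in MafA, a transcription factor that drives insulin gene expression in beta cells. The series' title links this variant to maturity-onset diabetes of the young. The 18 libraries fall into 4 groups by sex and genotype, with 4 male WT, 4 male S64F/+, 5 female WT and 5 female S64F/+ libraries. The library totals were 19.3, 40.5, 31.5 and 29.9 M counts in male WT and 61.6, 29, 44.8 and 38.2 in male S64F/+ islets. They were 108.7, 64.1, 23.5, 46.9 and 45.5 in female WT and 44.3, 21.8, 26.8, 55.5 and 57.4 in female S64F/+ islets, and the median over all libraries was 42.4. Of 53801 listed mouse genes, 18364 passed the filter on low counts and were tested. Replicates of a group correlated at 0.960 to 0.988 across genes. Expression is given as CPM with the SD over libraries, with n = 4 for each male group and n = 5 for each female group, and log2 fold changes with their SE. The labels do not state that replicates came from separate animals, so p-values measure only the spread between these libraries.

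Mafa transcript itself was lower in S64F/+ islets of both sexes. Mafa (ENSMUSG00000047591, GRCm38 chromosome 15, 75745490 to 75748228, minus strand) fell from 905 ± 80.8 CPM in male WT to 197 ± 52.3 CPM in male S64F/+ islets, a log2 fold change of -2.20 ± 0.22 (edgeR adjusted p 1.77e-06). In females it fell from 639 ± 117 to 160 ± 49.8 CPM, a log2 fold change of -2.0 ± 0.20 (edgeR adjusted p 1.60e-06). The effect did not differ detectably between the sexes, with a difference of -0.20 ± 0.29 on the log2 scale (edgeR adjusted p 0.704), or 0.03 with library-size scaling. Mafa also did not differ detectably between male and female WT islets (log2 difference 0.50 ± 0.20, edgeR adjusted p 0.195) or between male and female S64F/+ islets (0.30 ± 0.20, edgeR adjusted p 0.311). A gene count sums both alleles, so it does not check the genotype labels. Xist, the RNA that silences an X chromosome in females, was at 901 ± 140 and 827 ± 244 CPM in the female groups and at 0.206 ± 0.181 and 0.138 ± 0.0706 CPM in the male groups. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to between 176 and 212 CPM in every male library and to at most 3.66 CPM in a female library, so all 18 libraries matched their sex labels.

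**Figure D1:**
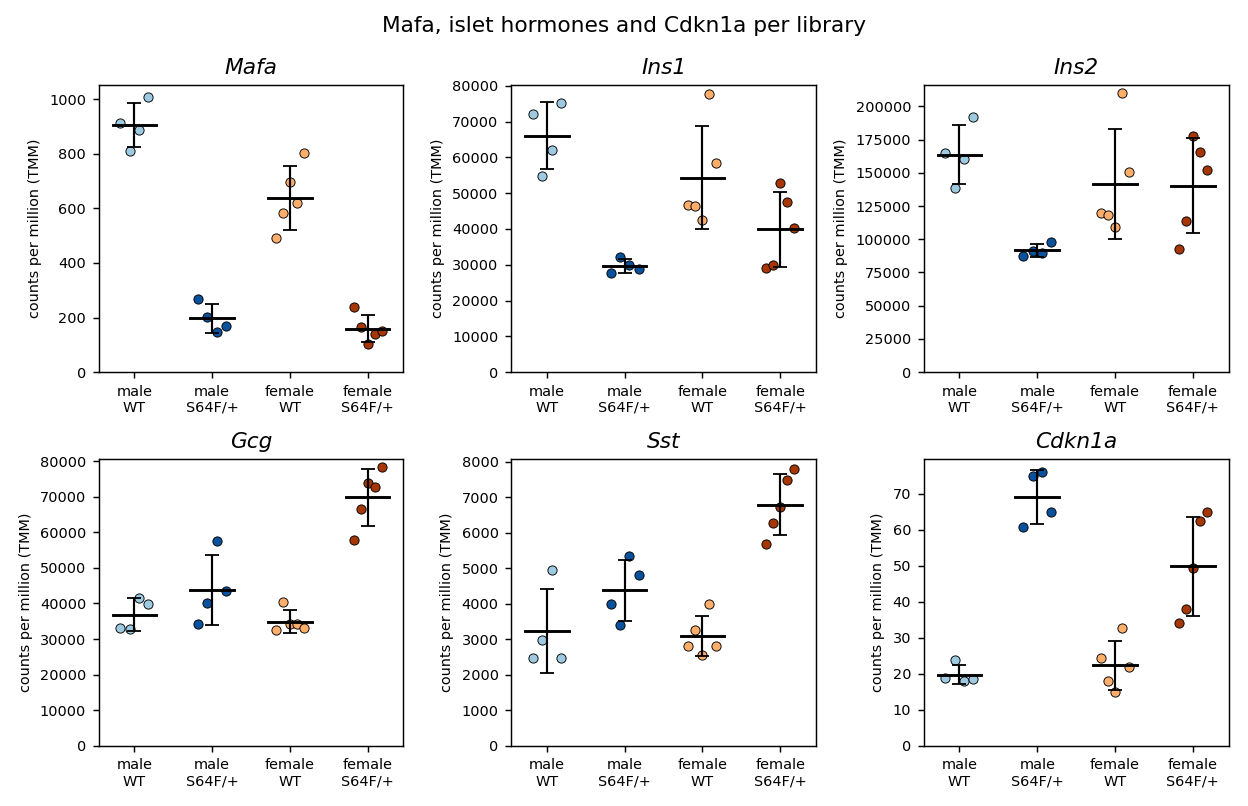
CPM (TMM-scaled, y axis) of Mafa, Ins1, Ins2, Gcg, Sst and Cdkn1a in each library (points) of the 4 groups (x axis), with the group mean (thick line) and SD (error bar), n = 4 per male and 5 per female group. Mafa was lower and Cdkn1a higher in every S64F/+ library than in any WT library of the same sex, whereas Ins2 separated the genotypes in males and Gcg and Sst separated them in females.

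The comparison of male S64F/+ with male WT islets asked what the variant changes in the sex in which the study's title places the beta-cell dysfunction. The largest rises by the fixed rule were in genes near absent from male WT islets. Il4, the cytokine of type-2 immunity, had 0 counts in the male WT libraries and 2.94 ± 0.537 CPM in S64F/+ islets, at least 111-fold higher against a floor of 3 counts over the group (edgeR adjusted p 1.27e-05). Il13ra2, the decoy receptor for interleukin-13, also had 0 counts in male WT islets and rose to 6.78 ± 3.15 CPM, at least 246-fold higher (edgeR adjusted p 5.36e-07). Rnase2a, of the eosinophil ribonuclease family, and Chil4, a chitinase-like protein, had 0 counts in WT as well and rose to 5.14 ± 2.07 and 4.74 ± 4.54 CPM, at least 196-fold and 165-fold higher. The call of Chil4 (edgeR adjusted p 0.0473) was lost in 10 of the 18 fits that left out 1 library, with the highest value of 0.0881 without male WT 4. H2-M2, a non-classical class I antigen-presenting gene, reached 9.96 ± 3.28 CPM in S64F/+ islets against 2 counts over the male WT group, a ratio of 546 (95% counting interval 151 to 4510). These floors and intervals cover counting error only. The largest falls included Slc14a2, a urea transporter (log2 fold change -3.35 ± 0.38), and Cntnap2, a neurexin-family adhesion protein (69.5 ± 5.54 to 7.79 ± 1.07 CPM, -3.16 ± 0.28). The others were Xlr4a (-3.04 ± 0.86), Kcnj12, an inwardly rectifying potassium channel (-2.99 ± 0.26), Msln, which encodes mesothelin (-2.75 ± 0.40), and the cadherin Cdh7 (-2.64 ± 0.35). Of these, Xlr4a lost its call without male WT 2 (edgeR adjusted p 0.0698, against 0.0142 with all libraries).

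Genes of beta-cell identity fell in male S64F/+ islets. Of 27 members tested, 19 fell and 1 rose (20 and 1 adjusted over the list alone), with a median log2 fold change of -0.56 (camera adjusted p 1.11e-10, and 0.00957 with an estimated correlation). Ins1 fell from 66110 ± 9418 to 29660 ± 1905 CPM (log2 fold change -1.16 ± 0.20, edgeR adjusted p 0.000380) and Ins2 from 163700 ± 22000 to 91640 ± 4704 CPM (-0.84 ± 0.21, edgeR adjusted p 0.00611). Ucn3, the urocortin peptide of mature beta cells, fell from 542 ± 50.5 to 192 ± 15.8 CPM (-1.50 ± 0.11, edgeR adjusted p 4.37e-08), and the transcription factor Mnx1 from 29.2 ± 2.62 to 11 ± 0.990 CPM. The member that rose was Pcsk1, a proinsulin-processing convertase (0.45 ± 0.12). The reported MafA targets, 11 of which are also in the identity list, gave 12 lower and 1 higher of 16 (12 and 2 adjusted over the list alone; median -0.60, camera adjusted p 9.09e-07, and 0.0478 with an estimated correlation), among them Ppp1r1a, an inhibitor of protein phosphatase 1 (-1.25 ± 0.10). The beta-cell disallowed genes, which mature beta cells keep at low levels, moved the other way. Of 25, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 1.57 (camera adjusted p 1.57e-09, but adjusted p = 0.237 with an estimated correlation). Igf1 rose from 2.95 ± 0.571 to 17.8 ± 4.27 CPM and Tgm2, transglutaminase 2, from 10.5 ± 1.59 to 73.0 ± 19.4 CPM, whereas the water channel gene Aqp4 fell (-1.50 ± 0.20). Pdgfra of this list is also a stellate-cell marker. In the same libraries the mean log2 CPM of stellate and fibroblast markers was higher by 2.26 ± 0.36, of Schwann-cell markers by 1.57 ± 0.23, of ductal markers by 1.36 ± 0.15 and of macrophage markers by 1.13 ± 0.12. Of 12 markers of immature or dedifferentiated beta cells, Aldh1a3, Sox9, Npy and Cd81 rose and none fell (4 adjusted over the list alone; median 0.26, camera adjusted p 0.0129, and adjusted p = 0.108 with an estimated correlation). Aldh1a3, a retinaldehyde dehydrogenase, had the largest log2 fold change of these, 2.48 ± 0.54. With library-size scaling the list medians were -0.33 for identity genes, -0.38 for reported MafA targets and 0.49 for immature markers, the last also 0.40 without male WT 3. Stimulus-secretion coupling genes went both ways, with 7 higher and 10 lower of 36 (7 and 12 adjusted over the list alone), and the list did not pass (median -0.16, or 0.06 with library-size scaling; camera adjusted p 0.138). The T-type calcium channel gene Cacna1h rose (1.15 ± 0.22, edgeR adjusted p 0.000769), and Rapgef4, a cAMP sensor of exocytosis, fell (-0.37 ± 0.07, edgeR adjusted p 0.000668), a call that library-size scaling ended (edgeR adjusted p 0.227).

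Senescence-associated secretory factors rose in male S64F/+ islets, with 22 of 37 higher and none lower (24 adjusted over the list alone), a median of 1.22 (camera adjusted p 1.81e-10, and 0.0316 with an estimated correlation). Plat, tissue plasminogen activator, rose from 8.08 ± 1.5 to 59.2 ± 11.9 CPM (log2 fold change 2.87 ± 0.15, edgeR adjusted p 3.39e-09), and Mmp12, macrophage elastase, from 2.24 ± 1.34 to 21.8 ± 3.41 CPM (3.28 ± 0.33, edgeR adjusted p 1.44e-06). In the same libraries the mean log2 CPM of macrophage markers was higher by 1.13 ± 0.12 and that of stellate-cell and fibroblast markers by 2.26 ± 0.36. The list of senescence arrest and p53 targets gave 8 higher and 2 lower of 28 (8 and 3 adjusted over the list alone) and did not pass as a list (median 0.11, camera adjusted p 0.203). Cdkn1a, the cyclin-dependent kinase inhibitor induced by p53, rose from 19.8 ± 2.65 to 69.2 ± 7.55 CPM (1.80 ± 0.23, edgeR adjusted p 2.13e-05), and Serpine2, a serpin protease inhibitor, from 17.0 ± 2.34 to 36.6 ± 2.76 CPM. The 2 members that fell were Cdkn2c (-0.64 ± 0.16) and Bax (-0.47 ± 0.11). Cdkn2a, the other kinase inhibitor locus commonly used as a senescence marker, was at 0.523 ± 0.113 CPM in WT and 0.397 ± 0.136 CPM in S64F/+ islets and did not differ detectably (edgeR adjusted p 0.497).

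Cholesterol and fatty acid synthesis genes fell in male S64F/+ islets, with 20 of 27 lower and none higher (21 adjusted over the list alone), a median of -0.57 (camera adjusted p 8.63e-10, but adjusted p = 0.132 with an estimated correlation). Insig1, a sterol-sensing regulator, fell from 162 ± 10.7 to 74.3 ± 10.2 CPM. The list's median was -0.35 with library-size scaling. In the libraries of this paragraph the markers of other cells were higher, by 2.26 for stellate, 1.57 for Schwann, 1.36 for ductal, 1.13 for macrophage and 0.95 ± 0.17 for delta cells in mean log2 CPM. Nuclear-encoded oxidative phosphorylation genes passed as a list in the downward direction, but only Ndufb8, Sdha and Uqcrc2 of 42 fell on their own (1 adjusted over the list alone; median -0.16, camera adjusted p 0.0163, and adjusted p = 0.696 with an estimated correlation). That list's call was lost without male WT 4 (camera adjusted p 0.0747), and with library-size scaling (0.271), which turned its median to 0.07. The Uqcrc2 call (edgeR adjusted p 0.0395) was lost in 7 of the 18 fits that left out 1 library, with the highest value of 0.152 without male WT 4, and with library-size scaling (log2 fold change -0.01, edgeR adjusted p 0.924). The interferon response and antigen presentation list passed upward with 6 higher and Usp18 lower of 30 (5 and 1 adjusted over the list alone; median 0.34, camera adjusted p 0.0204, and adjusted p = 0.625 with an estimated correlation). This call was lost without male WT 4 (camera adjusted p 0.0966) or male S64F/+ 3 (0.0661) and with library-size scaling (0.0956), where the median was 0.55, and the median was 0.54 without male WT 2. Isolation stress and immediate early genes, a handling control, gave Egr2, Ier3, Hspb1 and Klf6 higher of 19 (4 adjusted over the list alone; median 0.43, camera adjusted p 0.0223, and adjusted p = 0.677 with an estimated correlation). This call was lost without male WT 2 (camera adjusted p 0.0695) or male S64F/+ 4 (0.0766) and with library-size scaling (0.0956). Tph1, the rate-limiting enzyme of serotonin synthesis, rose from 0.0421 ± 0.0842 to 9.59 ± 4.33 CPM and Egln3, a prolyl hydroxylase of hypoxia-inducible factors, from 1.08 ± 0.435 to 15.6 ± 6.05 CPM, although their lists did not pass. Those lists were prolactin response (Tph1 higher and Ivd lower of 11, 1 and 1 adjusted over the list alone, camera adjusted p 0.504) and hypoxia and glycolysis (5 higher and 3 lower of 24, 7 and 4 adjusted over the list alone, camera adjusted p 0.207). With library-size scaling the hypoxia list passed upward (camera adjusted p 0.0289). That scaling ended the calls of Ivd, Gsr, Sod2, Taldo1, Xbp1, Hyou1 and Creld2 (edgeR adjusted p 0.104 to 0.574). The unfolded protein response list did not pass either, with Trib3, Eif4ebp1 and Ern1 higher and Xbp1, Sdf2l1, Hyou1, Creld2 and Ero1lb lower of 27 (3 and 5 adjusted over the list alone, camera adjusted p 0.157). Nor did cell proliferation (E2f1 lower of 30, also 1 adjusted over the list alone, camera adjusted p 0.197) or the antioxidant response (Slc7a11, Cat and Gsta4 higher and Sod2, Gsr and Taldo1 lower of 23, 2 and 3 adjusted over the list alone, camera adjusted p 0.976). The unfolded protein response list passed downward without male WT 2 (camera adjusted p 0.0165) or male S64F/+ 4 (0.0470), and cell proliferation without male WT 4 (0.0410). Of 13 mitochondrially encoded genes, mt-Co1 fell (0 adjusted over the list alone; median of the list -0.27, camera adjusted p 0.0838). The list passed downward without male WT 1 (camera adjusted p 0.0313) or male WT 2 (0.0324), with library-size scaling (0.0169, median -0.04) and with the replicate block (0.0466). The mt-Co1 call (edgeR adjusted p 0.0458) was lost in 10 of the 18 fits that left out 1 library (up to 0.134, without male WT 4). Library-size scaling ended it too (0.195).

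Markers of several other islet cell types rose in male S64F/+ islets, those of stellate cells and fibroblasts most. Of 14 stellate and fibroblast markers 12 rose (14 adjusted over the list alone; median 2.40, camera adjusted p 2.29e-07, but adjusted p = 0.291 with an estimated correlation), such as the collagen gene Col6a3 (27.3 ± 5.01 to 87.4 ± 16.8 CPM) and the growth factor receptor gene Pdgfrb (21.7 ± 5.87 to 65.1 ± 4.44 CPM). The mean log2 CPM of these markers was higher by 2.26 ± 0.36 (exact permutation p 0.0286, two-sided, the smallest that 4 against 4 libraries allow, and 0.0409 adjusted over 10 cell types). Endothelial markers rose by 9 of 14 with Esm1 lower (11 and 1 adjusted over the list alone; median 0.70, camera adjusted p 0.000296, and adjusted p = 0.461 with an estimated correlation). Pecam1, an endothelial adhesion molecule, went from 57.5 ± 9.62 to 169 ± 18.1 CPM. Macrophage markers rose by 10 of 14 with C1qa lower (10 and 1 adjusted over the list alone; median 1.23, camera adjusted p 4.01e-06, and adjusted p = 0.132 with an estimated correlation). Ductal markers rose by 9 of 12 (10 higher and 1 lower adjusted over the list alone; median 1.36, camera adjusted p 3.63e-05, and adjusted p = 0.0587 with an estimated correlation), with Spp1, osteopontin, going from 47.9 ± 11 to 304 ± 41.5 CPM. Delta-cell markers rose by 7 of 8 (8 adjusted over the list alone; median 0.93, camera adjusted p 0.000107, and adjusted p = 0.108 with an estimated correlation). Of 10 Schwann-cell markers Sox10, Gfap, Gfra3 and Ngfr rose (5 adjusted over the list alone; median 1.6, camera adjusted p 0.000816, and adjusted p = 0.317 with an estimated correlation). Alpha-cell markers did not pass as a list (Slc38a5 higher and Dpp4 lower of 12, 1 and 1 adjusted over the list alone, camera adjusted p 0.166). The alpha-cell hormone gene Gcg had a log2 fold change of 0.25 ± 0.15 (edgeR adjusted p 0.226) and the delta-cell hormone gene Sst one of 0.44 ± 0.20 (edgeR adjusted p 0.118). With library-size scaling both passed (edgeR adjusted p 0.0171 and 0.0200), and Sst also passed with the replicate block (0.0356) and without male WT 3 (log2 fold change 0.73, edgeR adjusted p 0.00589). None of 6 PP-cell (camera adjusted p 0.0838), 23 acinar (0.203) or 6 red blood cell genes (0.504) passed, also adjusted over the list alone. Of 10 lymphocyte markers Cd4 and Ccr7 rose and Cd79a fell (2 and 1 adjusted over the list alone, camera adjusted p 0.504), and of 4 adipocyte markers Plin4 rose (2 adjusted over the list alone, camera adjusted p 0.239). PP-cell markers passed upward without male WT 3 (camera adjusted p 0.0402). The acinar list stood apart downward without male WT 2 (camera adjusted p 8.36e-05) and with library-size scaling (0.00276).

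In all, 5071 of 18364 genes (27.6%) changed between male S64F/+ and male WT islets, 2819 higher and 2252 lower, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Changes of at least 2-fold were mostly rises, 1740 against 363 falls. With library-size scaling the balance became 4248 higher and 666 lower, since that scaling placed the median of all genes at 0.19 instead of -0.03, so directions here are relative to the scaling by trimmed mean of M values. The preset-correlation list test called 15 of 29 lists, and other splits of the 8 male libraries often called as many, so the counts of members rest on the gene test.

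In female S64F/+ islets the largest rises again included genes that were near absent from WT islets. Il4 rose from 0.0422 ± 0.0718 to 1.43 ± 0.616 CPM (edgeR adjusted p 4.61e-05), H2-M2 from 0.130 ± 0.122 to 3.04 ± 1.26 CPM (edgeR adjusted p 1.58e-05) and Retnla, a resistin-like protein of alternatively activated macrophages, from 0.0873 ± 0.0575 to 2.35 ± 1.40 CPM (edgeR adjusted p 3.34e-05). Igfbpl1 rose from 0.223 ± 0.334 to 9.63 ± 4.94 CPM and Adamdec1, a metalloprotease-like gene, from 0.0331 ± 0.0519 to 1.35 ± 0.494 CPM. Rnase2a was at 0.292 ± 0.329 CPM against 3 counts over the WT group, a ratio of 33.6 (95% counting interval 11 to 167). The largest falls were those of Cntnap2 (65.6 ± 13.8 to 6.08 ± 3.19 CPM, log2 fold change -3.42 ± 0.25, edgeR adjusted p 1.76e-07), Slc14a2 (-3.28 ± 0.34), Kcnj12 (-3.15 ± 0.24), the potassium channel gene Kcng3 (-3.05 ± 0.45), the serine protease gene Tmprss4 (-2.88 ± 0.23) and the glycine receptor gene Glra1 (-2.79 ± 0.62).

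Beta-cell identity genes fell in female S64F/+ islets too, 19 of 27 lower with Pcsk1 and Cpe, carboxypeptidase E, higher (21 and 2 adjusted over the list alone; median -0.45, camera adjusted p 5.99e-08, and 0.0332 with an estimated correlation). Mnx1 fell from 37.9 ± 7.12 to 12.8 ± 1.80 CPM. The insulin genes did not pass, with Ins1 at 54390 ± 14360 in WT and 39910 ± 10540 CPM in S64F/+ islets (log2 fold change -0.45 ± 0.18, edgeR adjusted p 0.0882) and Ins2 at 141700 ± 41270 and 140400 ± 36000 CPM (-0.01 ± 0.19, up to 0.17 without female WT 4, edgeR adjusted p 0.971). Ins1 passed with library-size scaling (edgeR adjusted p 0.0255) and without female S64F/+ 3 (edgeR adjusted p 0.0370), and also with DESeq2. Of 16 reported MafA targets 11 fell and Pcsk1 rose (13 and 1 adjusted over the list alone; median -0.46, camera adjusted p 1.91e-06, and 0.0484 with an estimated correlation), with Pcx, pyruvate carboxylase, going from 227 ± 37.3 to 106 ± 14.4 CPM. Of 36 stimulus-secretion coupling genes 16 fell and Cacna1h, Ryr3 and Stx1a rose (18 and 3 adjusted over the list alone; median -0.19, camera adjusted p 0.000715, but adjusted p = 0.425 with an estimated correlation). Those that fell included the calcium release channel gene Itpr3 (-0.83 ± 0.10). Of 25 disallowed genes Oat, Lmo4 and Igf1 rose and Aqp4 fell (3 and 1 adjusted over the list alone; median 0.46, camera adjusted p 0.00788, and adjusted p = 0.700 with an estimated correlation). In the same libraries the mean log2 CPM of alpha-cell markers was higher by 0.75 ± 0.10 and of macrophage markers by 0.67 ± 0.21. The median of the disallowed genes was 0.24 without female S64F/+ 3. Of 12 immature or dedifferentiated markers 5 rose, among them Sox9, Npy, Cd81 and Fev (6 adjusted over the list alone; median 0.66, camera adjusted p 0.000853, and 0.0484 with an estimated correlation). Npy, neuropeptide Y, rose from 30.6 ± 9.48 to 195 ± 41.0 CPM.

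Cdkn1a rose in females from 22.4 ± 6.80 to 49.8 ± 13.9 CPM (log2 fold change 1.16 ± 0.20, edgeR adjusted p 0.000509), and Cdkn2a, at 0.335 ± 0.0892 and 0.266 ± 0.114 CPM, did not differ detectably (edgeR adjusted p 0.547). Of 28 senescence arrest and p53 targets 9 rose and Igf1r fell (9 and 1 adjusted over the list alone; median 0.27, camera adjusted p 0.0413, and adjusted p = 0.321 with an estimated correlation). That list call was lost without female WT 3 (camera adjusted p 0.114), female S64F/+ 4 (0.0696) or female S64F/+ 5 (0.0704), and its median was 0.115 without female S64F/+ 3. Of 37 senescence-associated secretory factors 9 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.50, camera adjusted p 0.00386, and adjusted p = 0.321 with an estimated correlation). Plat rose from 8.97 ± 0.917 to 29.6 ± 2.92 CPM and Mmp12 from 1.82 ± 0.426 to 6.64 ± 1.62 CPM. The macrophage marker level was higher by 0.67 ± 0.21 in the same libraries, on the log2 scale.

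Oxidative phosphorylation genes rose in female S64F/+ islets, with 20 of 42 nuclear-encoded members higher and none lower (25 adjusted over the list alone; median 0.35, camera adjusted p 2.71e-07, but adjusted p = 0.463 with an estimated correlation). Ndufs4, a complex I subunit, went from 28.3 ± 3.76 to 42.7 ± 10.6 CPM and Atp5o, an ATP synthase subunit, from 44.9 ± 4.79 to 65.6 ± 17.4 CPM. Of 13 mitochondrially encoded genes mt-Nd1 rose (1 adjusted over the list alone; median 0.39, camera adjusted p 0.00904, and adjusted p = 0.606 with an estimated correlation). Without female S64F/+ 3, whose mitochondrially encoded level stood above the others, the list did not pass (camera adjusted p 0.0535, median 0.22), and mt-Nd1 lost its call in 3 of the 18 fits that left out 1 library, with the highest edgeR adjusted p, 0.0592, also without that library. Cholesterol and fatty acid synthesis genes fell, 11 of 27 (16 adjusted over the list alone; median -0.36, camera adjusted p 4.48e-06, and adjusted p = 0.321 with an estimated correlation). The antioxidant response gave Gpx1, Gpx3, Sod1, Prdx1 and Tkt higher and Nqo1 and Gsr lower of 23 (5 and 2 adjusted over the list alone; median 0.12, camera adjusted p 0.0413, and adjusted p = 0.700 with an estimated correlation). Cell proliferation gave Mcm2, Mcm3 and Mcm5 higher and E2f1 lower of 30 (1 and 1 adjusted over the list alone; median 0.24, camera adjusted p 0.0209, and adjusted p = 0.760 with an estimated correlation). Isolation stress genes passed with Klf4 alone of 19 (1 adjusted over the list alone; median 0.42, camera adjusted p 0.0193, and adjusted p = 0.728 with an estimated correlation). These last 3 calls were each lost without single female libraries, up to a camera adjusted p of 0.167 without female WT 2 for the antioxidant response, 0.283 without female WT 1 for cell proliferation and 0.140 without female S64F/+ 5 for isolation stress. Single libraries also moved their medians, to 0.19 and 0.18 without female WT 4 and female S64F/+ 2, to 0.11 and 0.37 without female WT 1 and female WT 2, and to 0.65 without female WT 4, in the same order. In these libraries the mean log2 CPM was higher by 0.75 ± 0.10 for alpha-cell and 0.70 ± 0.09 for delta-cell markers. Lists that did not pass were the unfolded protein response (Dnajb9, Trib3, Pdia6 and Eif4ebp1 higher and Edem1 and Ero1lb lower of 27, 6 and 2 adjusted over the list alone, camera adjusted p 0.144) and interferon response and antigen presentation (Ifih1 higher, Stat2 and Usp18 lower of 30, 0 adjusted over the list alone, 0.806). Nor did hypoxia and glycolysis (Egln3, Tpi1 and Gpi1 higher, Pdk1 and Ero1l lower of 24, 3 and 2 adjusted over the list alone, 0.438) and prolactin response (Tph1 and Gbp8 higher, Prlr and Wipi1 lower of 11, 3 and 4 adjusted over the list alone, 0.683). The unfolded protein response list passed upward without female S64F/+ 2 (camera adjusted p 0.0410). The Ifih1 call (edgeR adjusted p 0.0287) was lost in 5 of the 18 fits that left out 1 library, with the highest value of 0.0797 without female WT 1, and with library-size scaling (0.0760). Usp18 lost its call without female S64F/+ 2 (edgeR adjusted p 0.0562), and Wipi1 without female WT 3 (0.0539) and with the replicate block (0.0558).

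Markers of the other endocrine cells rose in female S64F/+ islets. Gcg went from 34910 ± 3100 to 69820 ± 7985 CPM (log2 fold change 1.00 ± 0.13, edgeR adjusted p 3.34e-05) and Sst from 3092 ± 570 to 6794 ± 865 CPM (1.14 ± 0.19, edgeR adjusted p 0.000245). Of 12 alpha-cell markers 10 rose and Dpp4 fell (10 and 1 adjusted over the list alone; median 0.83, camera adjusted p 2.08e-06, but adjusted p = 0.154 with an estimated correlation), among them Slc38a5, a glutamine transporter (31.5 ± 8.62 to 143 ± 31.1 CPM). Delta-cell markers rose by 6 of 8 (6 adjusted over the list alone; median 0.92, camera adjusted p 0.000243, and adjusted p = 0.154 with an estimated correlation), with Rbp4 going from 153 ± 20.6 to 339 ± 22.3 CPM. Of 6 PP-cell markers Ppy, Pyy, Tspan8, Sct and Folr1 rose (5 adjusted over the list alone, with a median of 0.81, camera adjusted p 0.00771, and adjusted p = 0.321 with an estimated correlation). Of these, Tspan8 (edgeR adjusted p 0.0572) and Ppy did not pass with the replicate block. The mean log2 CPM was higher by 0.75 ± 0.10 for alpha-cell, 0.70 ± 0.09 for delta-cell and 0.88 ± 0.22 for PP-cell markers, each with an exact permutation p of 0.00794, two-sided, the smallest that 5 against 5 libraries allow, and 0.0265 adjusted over 10 cell types. Macrophage markers rose by 9 of 14 (10 adjusted over the list alone; median 0.85, camera adjusted p 0.000106, and adjusted p = 0.289 with an estimated correlation). Of 12 ductal markers Sox9, Spp1 and Ambp rose (4 adjusted over the list alone; median 0.46, camera adjusted p 0.0297, and adjusted p = 0.321 with an estimated correlation), with a median of 0.28 without female S64F/+ 3. Of 14 stellate and fibroblast markers Col6a3 passed (0 adjusted over the list alone; median 0.49, camera adjusted p 0.156). With the replicate block this list passed (camera adjusted p 0.0414) and Col6a3 did not (edgeR adjusted p 0.0601, against 0.0448). Col6a3 also lost its call in 12 of the 18 fits that left out 1 library, with the highest edgeR adjusted p, 0.112, without female S64F/+ 4, and with library-size scaling (0.0931). The list also passed without female WT 2 (camera adjusted p 0.0318) or female S64F/+ 5 (0.00512). Endothelial markers did not pass (Esm1 lower of 14, 1 adjusted over the list alone, camera adjusted p 0.665). Nor did Schwann-cell markers (Gfra3 higher of 10, 1 adjusted over the list alone, 0.156) or lymphocyte markers (Cd4 and Lck higher and Cd79a lower of 10, 2 and 1 adjusted over the list alone, 0.438). The Schwann-cell list passed upward without female S64F/+ 4 (camera adjusted p 0.0399) or female S64F/+ 5 (0.0313). No call was made, also adjusted over the list alone, among 23 acinar (camera adjusted p 0.493), 4 adipocyte (0.665) or 6 red blood cell genes (0.807).

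In all, 3884 of 18364 genes (21.2%) changed between female S64F/+ and female WT islets, 1869 higher and 2015 lower, by the same edgeR test, and 380 rose and 392 fell by at least 2-fold. A fit of the 10 female libraries alone called 2587 genes. The list test called 18 of 29 lists, a count that other splits of the 10 female libraries also reached.

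**Figure D2:**
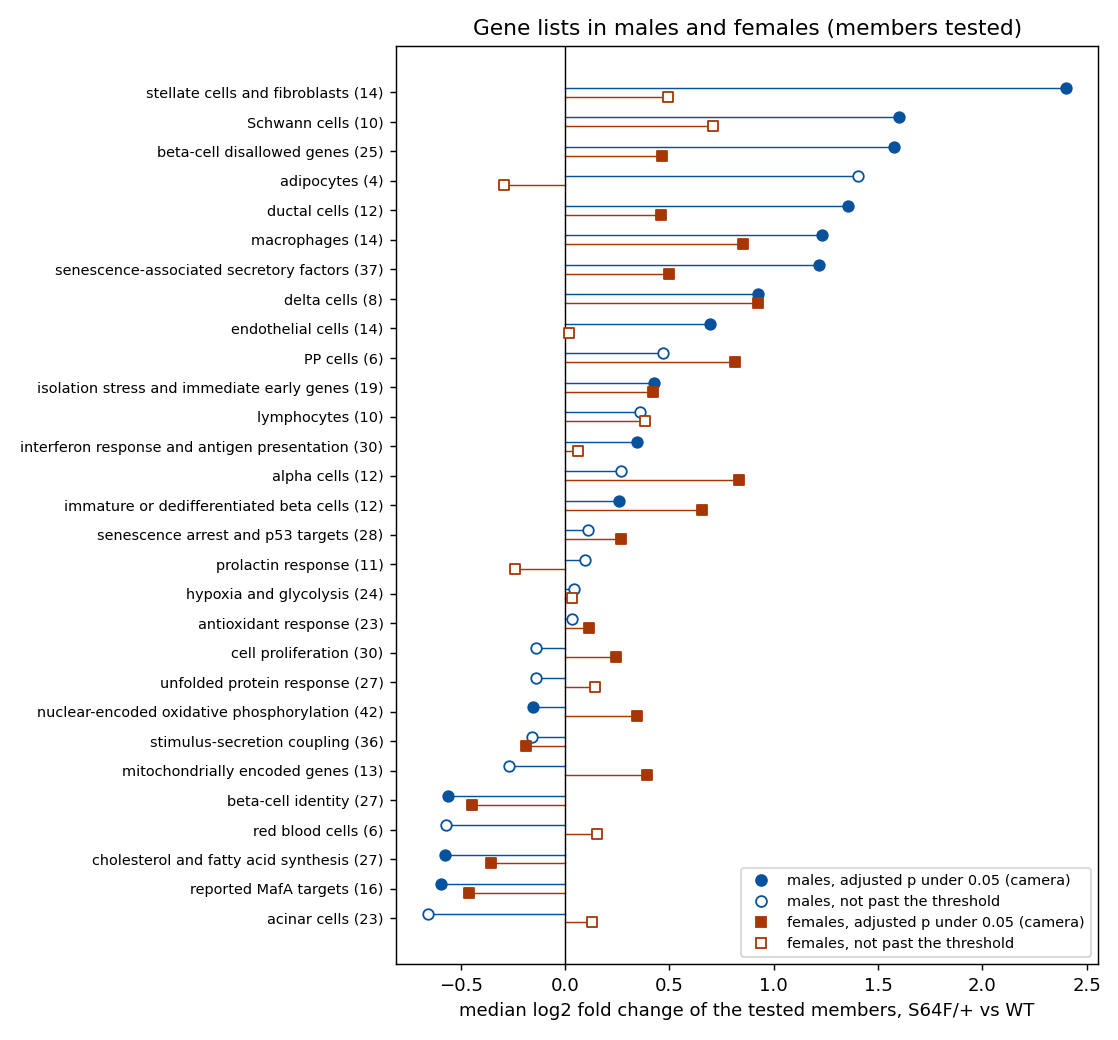
Median log2 fold change of the tested members (x axis) of the 29 gene lists (y axis, members tested in brackets), S64F/+ against WT, in males (blue circles) and females (red squares). Filled symbols mark camera adjusted p under 0.05 with a preset correlation. Stellate and fibroblast markers had a median of 2.40 in males and 0.49 in females, and oxidative phosphorylation genes one of -0.16 in males and 0.35 in females, where library-size scaling turned the male value to 0.07.

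The difference between the male and the female genotype effect was tested directly, since the title states a male bias. Col6a5, a collagen VI chain, went from 0.986 ± 0.376 to 96.5 ± 53.5 CPM in males and from 0.981 ± 0.480 to 3.79 ± 1.73 CPM in females, a difference of 4.61 ± 0.76 in log2 fold change (edgeR adjusted p 0.00926). Tph1 went from 0.0421 ± 0.0842 to 9.59 ± 4.33 CPM in males and from 0.179 ± 0.105 to 0.906 ± 0.303 CPM in females (difference 4.88 ± 0.97, edgeR adjusted p 0.0150, resting on 7 counts in the male WT group). Upk3a, which encodes a uroplakin, fell in males from 2.56 ± 0.456 to 0.669 ± 0.118 CPM and was at 2.61 ± 0.640 and 2.13 ± 0.570 CPM in females (difference -1.64 ± 0.34, edgeR adjusted p 0.0162). These 3 kept their call in every fit that left out 1 library. The other 9 genes with the largest differences, Muc6, H2-M2, Ankrd1 and Mc5r on the male-higher side and Ccl4, Edn2, Adam32, Tmsb15l and Pbk on the other, lost it in 5 to 14 of the 18, most often Ccl4 and Adam32. With the replicate block Muc6 (edgeR adjusted p 0.0691), H2-M2 (0.0694), Edn2 (0.0539), Adam32 (0.0598) and Pbk (0.0822) no longer passed, and with library-size scaling Tmsb15l and Pbk did not (edgeR adjusted p 0.0672 and 0.0840).

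Stellate and fibroblast markers had a median male minus female difference of 1.57, with Col6a3, Pdgfrb and Postn called of 14 (10 adjusted over the list alone; camera adjusted p 2.35e-06, but adjusted p = 0.392 with an estimated correlation). Endothelial markers had a median difference of 0.75, with Pecam1, Cdh5, Flt1 and Tie1 called of 14 (9 adjusted over the list alone; camera adjusted p 1.89e-05, and adjusted p = 0.392 with an estimated correlation). Pecam1 rose by 1.56 on the log2 scale in males and had 0.34 in females (difference 1.22 ± 0.22, edgeR adjusted p 0.00926). The secretory factors had a median difference of 0.86, with 5 of 37 called, among them Icam1, Plaur, Plat and Lamb1 (11 higher and 1 lower adjusted over the list alone; camera adjusted p 8.34e-07, and adjusted p = 0.278 with an estimated correlation). Disallowed genes had one of 0.96, with Zdhhc9, Zfp36l1, Tgm2, Gas6 and Igf1 called of 25 (8 adjusted over the list alone; camera adjusted p 5.03e-06, and adjusted p = 0.443 with an estimated correlation). Ucn3 fell further in males (difference -0.96 ± 0.14, edgeR adjusted p 0.00391). It was the identity gene called of 27 (3 adjusted over the list alone; median -0.15, or 0.10 with library-size scaling; camera adjusted p 0.00828, and adjusted p = 0.392 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had a median difference of -0.49, with Ndufa4, Ndufb3, Ndufb10, Ndufs3 and Sdhd called of 42 (25 adjusted over the list alone; camera adjusted p 6.40e-13, but adjusted p = 0.392 with an estimated correlation). The mitochondrially encoded genes had one of -0.72, with mt-Nd1 called of 13 (7 adjusted over the list alone; camera adjusted p 5.67e-05, and adjusted p = 0.392 with an estimated correlation). Alpha-cell markers had a median difference of -0.56, with Gcg, Tmem27 and Higd1a called of 12 (5 adjusted over the list alone; camera adjusted p 0.000707, and adjusted p = 0.392 with an estimated correlation). The difference for Gcg was -0.75 ± 0.20 (edgeR adjusted p 0.0429). With library-size scaling the medians were -0.25 for oxidative phosphorylation, -0.46 for mitochondrially encoded genes and -0.32 for alpha-cell markers. Reported MafA targets did not pass (Ppp1r1a and Ucn3 called lower of 16, 3 adjusted over the list alone, camera adjusted p 0.0715), nor did senescence arrest and p53 targets (0.665), for which no member was called (0 adjusted over the list alone). The list of reported MafA targets passed downward without male WT 3 (camera adjusted p 0.0353), female WT 1 (0.0482) or female S64F/+ 3 (0.0474). With an estimated correlation none of the 29 lists passed. Without male WT 4 the member calls of this paragraph ended (edgeR adjusted p up to 0.117), except those of Col6a3, Pecam1, Flt1, Icam1, Plaur, Plat, Zfp36l1, Tgm2, Gas6, Igf1, Ucn3 and Higd1a. With the replicate block Zdhhc9, Ndufa4, Ndufb3, Ndufb10 and mt-Nd1 did not pass (edgeR adjusted p 0.0519 to 0.0600). With library-size scaling Ppp1r1a, mt-Nd1 and the called oxidative phosphorylation and alpha-cell members did not (edgeR adjusted p 0.0655 to 0.141).

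In all, the genotype effect differed between the sexes for 821 of 18364 genes, 527 with a higher and 294 with a lower log2 fold change in males (interaction contrast, edgeR adjusted p under 0.05). The fold was larger in size in males for 611 of them, and 451 had opposite signs in the sexes. The count also rests on single libraries, as leaving out 1 moved it to between 253 (without male WT 4) and 2152 (without female S64F/+ 1), by over 1.5 times in 15 of 18 cases. With library-size scaling, which shifts the median of all genes in this contrast to 0.25, 1031 genes were higher and 30 lower.

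**Figure D3:**
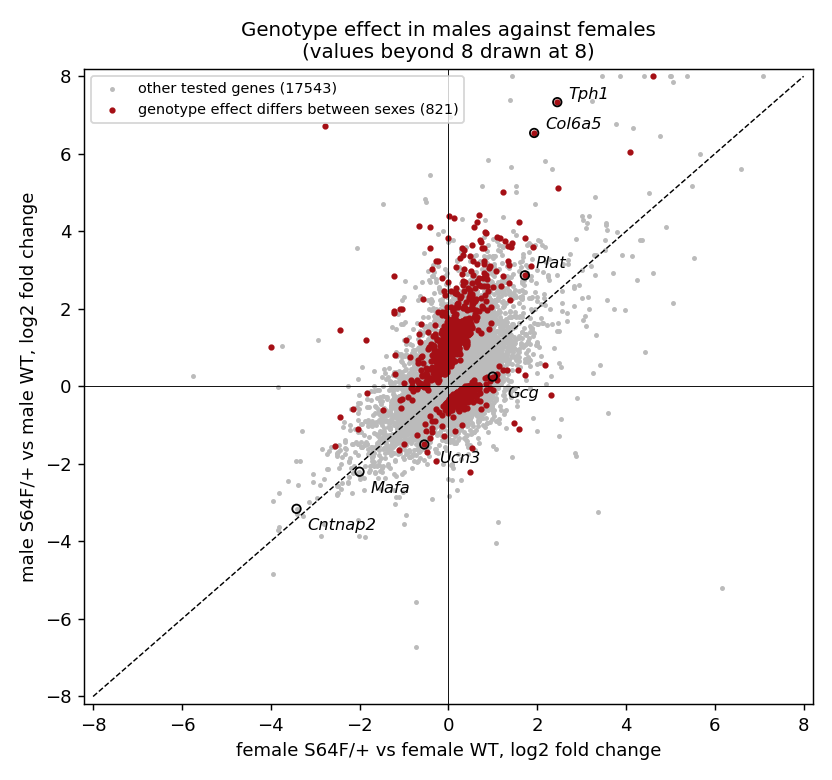
Log2 fold change of S64F/+ against WT in males (y axis) against females (x axis) for 18364 tested genes, with the 821 genes whose effect differed between the sexes in red and the line of equal effect dashed. Mafa and Cntnap2 lie near the line, Col6a5, Tph1 and Plat above it, and Gcg and Ucn3 below it.

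The male and the female genotype effects share no library. Across genes, which are not independent replicates, their log2 fold changes correlated with a Pearson r of 0.574 and a Spearman rho of 0.477. Of the genes called in both sexes, 777 were higher in both, against 287 that independent lists would share, and 1061 were lower in both, against 247. Opposite directions were found for 25, against 539. Of the 1838 genes changed the same way, 1162 had the larger fold in males. Slc14a2, Cntnap2 and Kcnj12 were among the 6 largest falls in each sex, and Il4, Rnase2a and H2-M2 among the 6 largest rises. Il4 and Rnase2a reached the rule's floor of 1 CPM, a mean over all 18 libraries, only with the male libraries counted. Their place in the female ranking is thus not independent of the males.

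Male and female WT islets were also compared. Beyond Xist and the Y-linked genes, the genes with the largest rises in males were Dscc1 and Cdc6, which act in DNA replication (2.11 ± 0.924 against 0.790 ± 0.211 CPM, and 4.92 ± 1.66 against 1.84 ± 0.615 CPM), Tcf24, a basic helix-loop-helix gene (35.9 ± 12.9 against 13.9 ± 1.79 CPM, log2 difference 1.37 ± 0.19, edgeR adjusted p 0.00197), and Exo1, a DNA exonuclease (2.88 ± 0.518 against 1.16 ± 0.465 CPM). Jhy was lower in males (1.67 ± 0.300 against 4.81 ± 0.590 CPM, log2 difference -1.52 ± 0.26, edgeR adjusted p 0.00820), as were Crp, Togaram2 and Robo3 (-2.07 ± 0.51, -1.45 ± 0.31 and -1.37 ± 0.33). Crp, Togaram2 and Robo3 lost their call in 10, 4 and 6 of the 18 fits that left out 1 library, with the highest edgeR adjusted p, 0.111, 0.0963 and 0.0935, without male WT 4. Exo1 lost its call without male WT 1 (edgeR adjusted p 0.0530), and Crp also with the replicate block (edgeR adjusted p 0.0691). With library-size scaling Exo1, Crp and Robo3 no longer passed (edgeR adjusted p 0.0512, 0.0556 and 0.0770). By the edgeR test 434 genes differed, 317 higher and 117 lower in males, of which 403 were autosomal, 25 on X and 6 on Y. The count fell to 71 without male WT 4 and to 112 with library-size scaling.

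Male and female S64F/+ islets differed in more genes. C7, a terminal complement component, was at 8.91 ± 1.72 CPM in males and 0.206 ± 0.0894 CPM in females (log2 difference 5.46 ± 0.46, edgeR adjusted p 1.98e-06), and Col6a5 at 96.5 ± 53.5 against 3.79 ± 1.73 CPM (4.70 ± 0.50, edgeR adjusted p 0.000117). Muc6, a gastric-type mucin, was at 4.90 ± 6.51 CPM in males against 1 count over the female group, a ratio of 780 (95% counting interval 140 to 30800). Trpm5, a cation channel of beta cells, was lower in males (26.5 ± 7.56 against 84.7 ± 30.5 CPM, -1.68 ± 0.23, edgeR adjusted p 0.000437), as were Serpina1d (-2.57 ± 0.44) and Fam196a (-1.95 ± 0.48). B4galnt2 (4.41 ± 1.39) and the acinar gene Reg1 (-1.74 ± 0.49) lost their call in 11 and 4 of the 18 fits that left out 1 library, with the highest edgeR adjusted p, 0.210 and 0.0728, without male S64F/+ 3. With the replicate block B4galnt2 and Reg1 had an edgeR adjusted p of 0.133 and 0.0700. By the edgeR test 2962 genes differed, 1470 higher and 1492 lower in males. With library-size scaling 2763 were higher and 374 lower, and the count fell to 1407 with the acinar level as a covariate and to 1651 without male S64F/+ 3.

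**Figure D4:**
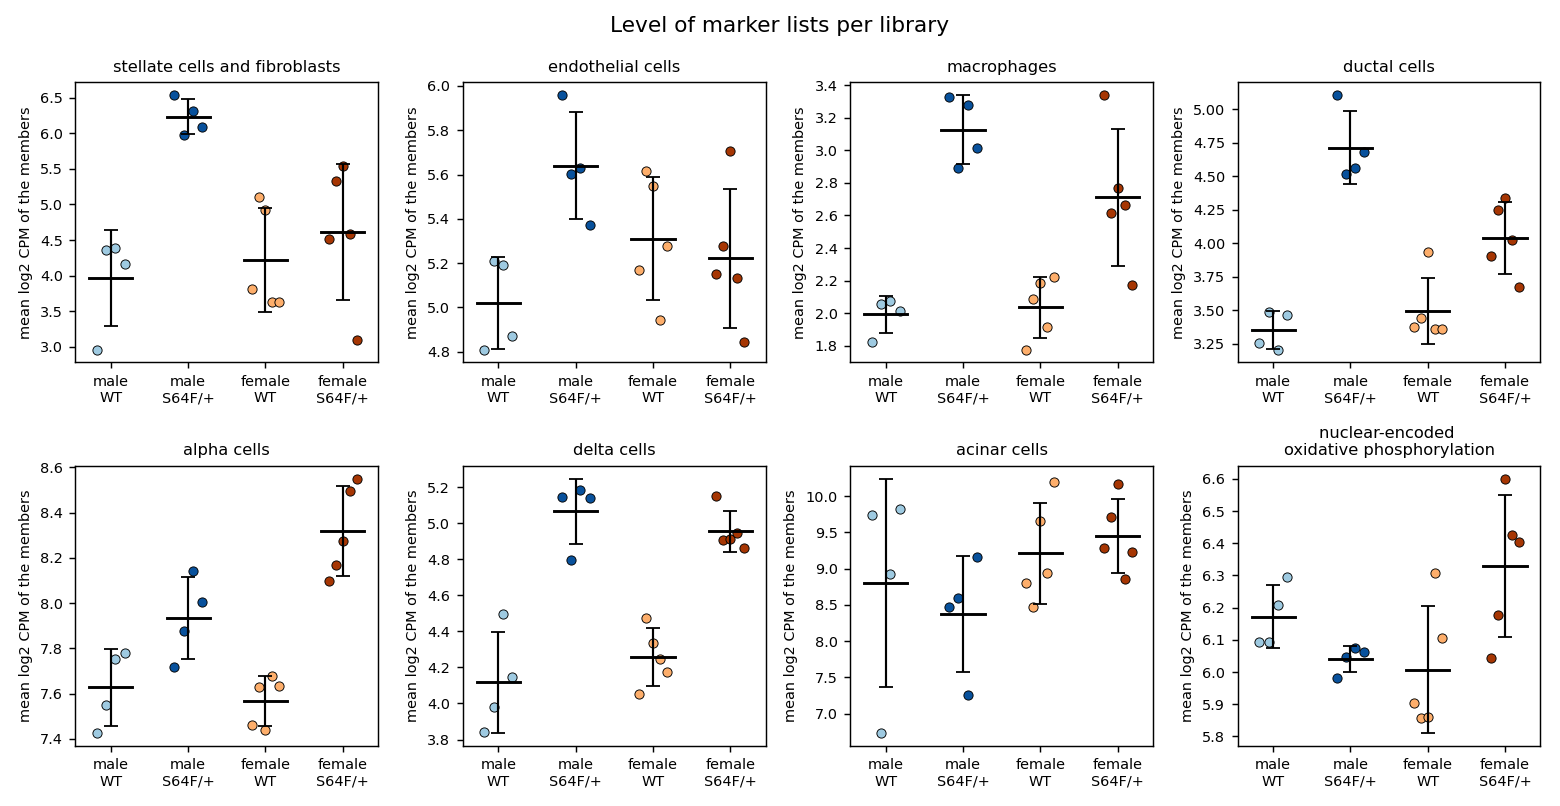
Mean log2 CPM of the members of 8 marker lists (y axis) in each library (points) of the 4 groups (x axis), with the group mean (thick line) and SD (error bar), n = 4 per male and 5 per female group. Stellate, endothelial, macrophage and ductal levels were higher in each male S64F/+ than in each male WT library, and alpha-cell and delta-cell levels were higher in each female S64F/+ than in each female WT library.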

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

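The comparisons of stellate and endothelial with alpha-cell markers, the acinar covariate test for stellate markers, the blocked test of oxidative phosphorylation genes, the test of X-linked homologues, library-size scaling of the lists that differed between the sexes and the homogeneity test in female libraries other than S64F/+ 3, the counts of Y-linked genes outside the 4 and the use of matched lists for scaling were chosen after the result was seen.

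The genotype effect differed between the sexes for 821 genes, of which those named are given here as the male minus the female log2 fold change, with edgeR adjusted p between 0.00391 (Ucn3) and 0.0494 (Cd68). The difference was 4.32 for H2-M2, 9.50 for Muc6, 4.88 for Tph1 and 4.09 for Plin4, fitted values that rest on 2, 1, 7 and 5 counts in the lowest group and are no measure of size. It was 4.61 for Col6a5, 3.83 for Ankrd1, 3.78 for Mc5r, -2.68 for Ccl4, -2.54 for Edn2, -1.64 for Upk3a, -1.43 for Adam32, -1.33 for Tmsb15l and -1.32 for Pbk. Leaving out 1 library ended the calls of Ankrd1, Mc5r, Adam32, Tmsb15l, Edn2 and H2-M2 with the highest edgeR adjusted p without male WT 4 (0.0748, 0.0773, 0.116, 0.100, 0.111 and 0.110). For Ccl4 the highest edgeR adjusted p was 0.104 without male WT 3, for Pbk 0.0837 without male S64F/+ 2 and for Muc6 0.982 without female WT 1. Among beta-cell and secretory genes it was -0.96 for Ucn3, -0.53 for Ppp1r1a, 1.72 for Igf1, 2.10 for Tgm2 and 1.14 for Plat. Among stress and metabolic genes it was 0.55 for Ddx58, 2.10 for Egln3, 0.85 for Ier3, -0.68 for mt-Nd1 and -0.45 for Tkt. Among cell-type markers it was 1.88 for Gpc6, 1.30 for Spp1, 1.22 for Pecam1, 0.87 for Tie1, 1.18 for Col6a3, 1.36 for Pdgfrb, 0.67 for Cd68, -0.75 for Gcg, -0.93 for Higd1a and -0.62 for Rbp4. Without male WT 4 Ppp1r1a, Ddx58, Ier3, mt-Nd1, Tkt, Gpc6, Tie1, Pdgfrb, Cd68, Gcg, Rbp4 and Plin4 did not pass (edgeR adjusted p 0.0522 to 0.117). With library-size scaling Ppp1r1a, mt-Nd1, Tkt, Gcg, Higd1a and Rbp4 did not (edgeR adjusted p 0.0664 to 0.237).

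For 17 lists the preset-correlation test gave a difference between the sexes, none of which held with an estimated correlation (adjusted p from 0.278 to 0.792). The median male minus female log2 difference was 0.96 for disallowed genes, 0.86 for secretory factors, 1.57 for stellate, 0.75 for endothelial, 1.08 for ductal, 0.40 for macrophage and 0.59 for Schwann-cell markers, and 0.22 for interferon response. It was -0.15 for beta-cell identity, -0.29 for the unfolded protein response, -0.37 for cell proliferation, -0.49 for oxidative phosphorylation, -0.72 for mitochondrially encoded genes, -0.22 for cholesterol and fatty acid synthesis, -0.18 for the antioxidant response, -0.56 for alpha-cell and -0.74 for acinar markers. With library-size scaling the medians of beta-cell identity (0.10), cholesterol synthesis (0.02) and the antioxidant response (0.06) were above 0. It brought those of the unfolded protein response to -0.05, cell proliferation to -0.16, oxidative phosphorylation to -0.25, mitochondrially encoded genes to -0.46, alpha-cell markers to -0.32, acinar markers to -0.48, macrophage markers to 0.62 and interferon response to 0.46. That scaling ended the calls of interferon response (camera adjusted p 0.15), the antioxidant response (0.100), macrophage (0.0843) and Schwann-cell markers (0.103). It gave calls upward for stimulus-secretion coupling (0.0446) and hypoxia and glycolysis (0.0446) and downward for red blood cell genes (0.0446). The calls of interferon response, antioxidant response, acinar, macrophage and Schwann-cell lists were each lost in 5 to 12 of the 18 fits that left out 1 library. Their highest camera adjusted p was 0.163 for interferon response (without male WT 4), 0.138 for the antioxidant response (without female WT 2), 0.390 for acinar markers (without male S64F/+ 3), 0.0890 for macrophage markers (without female S64F/+ 5) and 0.0831 for Schwann-cell markers (without female S64F/+ 1). Single libraries moved the median of interferon response to 0.46, 0.14 and 0.34 (without male WT 2, female WT 5 and female S64F/+ 1), of cholesterol synthesis to -0.14 (without male WT 4), of acinar markers to -0.47 (without male S64F/+ 3) and of Schwann-cell markers to 1.40 (without female S64F/+ 3).

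Single libraries stood apart from their group in 11 of 152 groups tested, where chance gives about 1 in 20. Cdkn1a was at 23.7 CPM in male WT 2, against 17.9 to 18.9 in the others. In mean log2 CPM, stellate markers were at 2.96 in male WT 1 (4.16 to 4.39 in the others), isolation stress genes at 6.56 in male WT 3 (5.87 to 5.95) and antioxidant genes at 5.71 in male S64F/+ 3 (5.35 to 5.41). Delta-cell markers were at 4.79 in male S64F/+ 2 (5.14 to 5.18). Gcg was at 40290 CPM in female WT 2 (32530 to 34320). Ductal markers were at 3.94 in female WT 3 (3.36 to 3.45) and red blood cell genes at -1.43 in the same library (0.28 to 0.87). Xist was at 1257 CPM in female S64F/+ 1 (659 to 760). In female S64F/+ 3 the mitochondrially encoded genes were at 6.4 (5.68 to 5.85) and the 4 Y-linked genes summed to 3.66 CPM (0 to 0.684).

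Stellate and fibroblast markers rose in male S64F/+ islets by a median log2 fold change of 2.40. A lower share of beta cells would raise the markers of other cells alike, but stellate markers rose by 1.95 ± 0.33 more than alpha-cell markers (exact permutation p 0.0286, the smallest possible, but 0.0515 adjusted over 9 cell types), which argues against it as the whole cause as far as the unadjusted test goes. Carry-over of acinar tissue and deeper sequencing were argued against by medians of 2.40 with the acinar level as a covariate and 2.44 with all male libraries thinned to the smallest total, each with 12 of 14 members called. Endothelial markers exceeded alpha-cell markers by 0.31 ± 0.23 (exact permutation p 0.229), so a lower beta-cell share stays open for them. Connective tissue carried over without acinar tissue, a change per cell and the genotype itself also stay open for the stellate markers and may act together.

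Oxidative phosphorylation genes rose in female S64F/+ islets by a median of 0.35. A bias by transcript length or expression level was argued against by 10000 lists matched on both, among which this median stood at percentile 100 (matched lists 0.06, with a central 95% range of -0.04 to 0.17). Structure shared by the female pairs, or by libraries 4 and 5 against 1 to 3 (also within the block), was argued against by the blocked test (fry p 0.00561) and by all 5 pairs being higher, by 0.12 to 0.74. A scaling error moves all genes alike, but the list lay 0.29 above the matched lists, which argues against it. A changed cell composition and the genotype stay open, as does chance for the number of lists, and the estimated-correlation adjusted p of this list was 0.463.

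Counts on the 4 Y-linked genes appeared in 7 of the 10 female libraries, at the highest rate in female S64F/+ 3 (98 counts, 3.66 CPM) and next in female WT 1 (236 counts, 2.17 CPM). Reads of X-linked homologues were argued against because 3 female libraries held 0 counts, among them female WT 2, where the highest female rate predicts 234.9. The 4 genes stood at 1.94%, 2.34%, 1.34% and 1.6% of their male level in female S64F/+ 3, which is consistent with 1 common source such as reads from a male library (homogeneity p 0.319). In female WT 1, with more counts, they stood at 1.26%, 1.33%, 0.99% and 0.58%, with 19 counts of Uty where 36.4 were expected (homogeneity p 0.00559, and at most 0.0310 against any single male library). That argues against reads from 1 of these male libraries as the whole source there, as far as counting error goes. In the other 5 libraries, with 4 to 38 counts, the p ran from 0.0228 to 0.448, unadjusted, so the source stays open. Of 4 other Y-linked genes 2 were no higher in males, such as Gm47283 (15.4 against 26.3 CPM). Gm29650 (3.53 CPM in males) had 1 count in female S64F/+ 3 and 3 in female WT 1, where the share of the 4 genes predicts 1.78 and 4.3. Gm4017 had 0 and 1 (0.167 and 0.402 predicted), too few to decide.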

How the results depend on the processing

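Scaling by library size alone, leaving out male WT 2 with male S64F/+ 3 and leaving out female WT 1 with female S64F/+ 3 were chosen after seeing the data, and the other alternatives were planned. The male and female gene counts stayed within 1.5 times of 5071 and 3884 under most settings. The exceptions in females were 2587 genes with a fit of only the groups compared and 2388 without female WT 1 and female S64F/+ 3. The interaction and the sex comparisons moved more. Without the filter on low counts, where more genes are tested, the interaction gave 481 genes, male against female WT 252 and male against female S64F/+ 1969, and the correlation of the male and female effects fell to 0.193. DESeq2 called 1928 genes for the interaction and 1067 between the WT groups. The fit of only the groups compared gave 226 between the WT groups. With the acinar level as a covariate the interaction gave 411, the WT groups 654 and the S64F/+ groups 1407. With limma-voom weights these counts were 4027, 963 and 7195, and the correlation was 0.447. Library-size scaling left 112 between the WT groups. Without male WT 2 and male S64F/+ 3 the interaction gave 472 and the S64F/+ groups 1557. The cause was not tested, beyond fewer libraries or more genes being tested where stated. RLE factors kept every count within 1.5 times.

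Library-size scaling moved the median log2 fold change of all genes to 0.19 in males, 0.25 in the interaction, 0.18 between the S64F/+ groups and -0.10 between the WT groups, against -0.01 in females. The share of higher calls went from 55.6% to 86.4% in males, from 64.2% to 97.2% in the interaction and from 49.6% to 88.1% between the S64F/+ groups. Male directions of small size therefore depend on the scaling.

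Leaving out each library in turn gave 3956 (without male WT 4) to 5545 genes in males, 2935 (without female WT 1) to 4988 in females, 253 to 2152 for the interaction, 71 to 643 between the WT groups and 1651 to 4298 between the S64F/+ groups. For the interaction, the counts beyond 1.5 times were 477, 355 and 253 without male WT 1, 3 and 4, and 344, 397, 363 and 450 without male S64F/+ 1 to 4. They were 516, 323, 459, 1945 and 496 without female WT 1 to 5, and 2152, 388 and 459 without female S64F/+ 1, 4 and 5. Between the WT groups they were 153, 181 and 71 without male WT 1, 3 and 4, and 166, 162 and 196 without female WT 1, 2 and 5. Between the S64F/+ groups they were 1693, 1826, 1651 and 1860 without male S64F/+ 1 to 4, and 1775 and 1801 without female S64F/+ 4 and 5. Lists called ranged from 14 to 17 in males, 16 to 18 in females and 12 to 17 for the interaction, and the correlation from 0.491 to 0.607.

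With an estimated correlation 3 lists were called in males, 3 in females and 0 for the interaction, against 15, 18 and 17. The lists kept were beta-cell identity and reported MafA targets in both sexes, secretory factors in males and immature markers in females. For the interaction 2 lists had an unadjusted camera p under 0.05 with an estimated correlation, and fry, which does not compare a list with other genes, called 9. Interaction list calls also ended with RLE factors for the antioxidant response (camera adjusted p 0.0510), and with the acinar covariate for it (0.0645) and interferon response (0.112). Without the filter on low counts male stimulus-secretion coupling (0.0424), unfolded protein response (0.0424), mitochondrially encoded genes (0.0146) and PP-cell markers (0.0376) passed. Without female WT 1 and female S64F/+ 3 the female calls of disallowed genes (0.112), mitochondrially encoded genes (0.112), the antioxidant response (0.0746) and ductal markers (0.0636) ended. Without male WT 2 and male S64F/+ 3 the male call of isolation stress genes ended (0.0972).

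With the replicate block the gene counts were 5101 in males, 3865 in females, 920 for the interaction, 343 between the WT groups and 2684 between the S64F/+ groups, the lists 16, 19 and 15, and the correlation 0.582. Same-numbered male libraries correlated at -0.249 to 0.189, below male WT 2 with male S64F/+ 3 (0.552), so the male libraries share only a number. Among lists the block ended the interaction calls of interferon response (camera adjusted p 0.0607) and macrophages (0.0626) and gave a call for male mitochondrially encoded genes (0.0466). Beyond these, the female stellate list and the genes given with a block value in the report, it changed no other call among the lists and the 172 results of genes named by the fixed rule. Of list members named outside that rule it also ended the calls of Sdha, Creld2, Gsta4 and Ccr7 in males (edgeR adjusted p 0.0547 to 0.202). In females it ended those of Trib3, Nqo1, Mcm2, Mcm3, Stat2, Gpi1, Gbp8 and Ppy (edgeR adjusted p 0.0563 to 0.107), and in the interaction those of Ddx58, Tkt and Cd68 (0.0517 to 0.0671). Library-size scaling ended 38 of 176 calls outside the rule, of list members and genes that it took for another comparison, in males, 20 of 129 in females and 16 of 43 in the interaction. It turned 2 in males, among them Sdha to 0.05. Leaving out 1 library ended 45, 40 and 28.

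Of 172 named gene results, 163 passed, and 130 of these kept their call under every alternative. A call was lost under at least 1 left-out library for 24 and under another of the planned settings for 22. No called result turned its direction. Of the uncalled, the sex difference of Mafa went from -0.20 to 0.03 with library-size scaling. Female Ins2 went from -0.01 to 0.15 with limma-voom weights and to between 0.01 and 0.17 without female WT 4 (the highest), female WT 5, female S64F/+ 1 or female S64F/+ 2. Under an alternative 3 that had not passed did, namely Gcg and Sst in males and Ins1 in females. Depth limits the genes near the floor, such as Tph1, Muc6, H2-M2 and Plin4.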

Other observations

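The list of alternatively activated macrophage genes, the genes named here and the hypothesis were chosen after the main test was seen, as were the comparison of its members above 1 CPM and the permutation of residuals. The test of the whole list was set before its own result was seen.

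Genes of alternatively activated macrophages rose in male S64F/+ islets beyond the fixed lists. Retnla rose from 0.103 ± 0.128 to 27.9 ± 11.3 CPM in males (edgeR adjusted p 1.37e-06) and from 0.0873 ± 0.0575 to 2.35 ± 1.40 CPM in females. The sex difference did not pass (2.81 ± 1.09, interaction edgeR adjusted p 0.132). Of 20 tested genes of the alternative activation list, which leaves out Retnla, Il4 and the other genes already seen, 16 rose in males and Lyve1 fell. Members near the floor pass the filter on low counts by being high in 1 group. Fcgr2b, an inhibitory Fc receptor, rose in males from 1.04 to 8.86 CPM (log2 fold change 3.07 ± 0.32, edgeR adjusted p 1.93e-06) and in females from 0.992 to 3.49 CPM (1.79 ± 0.27). This difference did not pass (interaction edgeR adjusted p 0.0705). Stab1, a scavenger receptor, rose from 12.95 to 30.0 CPM in males and was at 17.3 CPM in female WT and 14.4 CPM in female S64F/+ islets, a difference of 1.47 ± 0.26 (interaction edgeR adjusted p 0.00872). In females 8 of the list rose and Lyve1 and F13a1 fell.

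The macrophage markers held a member that went the other way. C1qb and C1qc rose in males (log2 fold changes 1.24 ± 0.15 and 1.45 ± 0.18), whereas their neighbour C1qa fell from 68.7 to 37.7 CPM (-0.86 ± 0.15, edgeR adjusted p 0.000383). In females C1qb and C1qc rose as well (0.88 ± 0.13 and 0.86 ± 0.16) and C1qa had -0.21 ± 0.14 (edgeR adjusted p 0.302). Its sex difference did not pass (interaction edgeR adjusted p 0.0655).

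As a hypothesis, macrophages of male S64F/+ islets may be shifted towards alternative activation beyond their number, and this was left undecided. The median log2 fold change of the list was 2.86 against 1.23 for the macrophage markers (permutation p 0.00939, two-sided, across genes, which are not independent), but the filter on low counts favours such a median. Among members with a mean of at least 1 CPM over all libraries the order turned, with 0.69 for 6 genes of the list against 1.23 for 13 macrophage markers (permutation p 0.0918). In females the medians of the whole lists were 0.81 and 0.85 (permutation p 0.734). Other cells, such as dendritic cells, express some of these genes, and 2 had 0 counts in male WT islets.

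Other splits of the libraries were counted for each fitted result. Chance was excluded for the male genes (1 of 35 splits gave as many as 5071, the highest other being 2). It was also excluded, each with 1 of 60, for the sex difference in WT (17 against 434) and S64F/+ islets (1304 against 2962). Chance was not excluded for the female genes (1 of 60, 3504 against 3884), as splits ignore the pairs. Nor was it for the correlation of the sexes' effects (1 of 60, 0.392 against 0.574). The split with 3504 exchanged only female WT 4 and female S64F/+ 1. The 16 splits that part all 5 pairs are too few for a share under 0.05 (highest other 43). For the interaction 3 of 60 splits gave as many as 821, which does not exclude chance, but the 2 larger ones (3186 and 3367), several times the real count, kept the male groups as they are and so carry the male effect. With the residuals of a model without the interaction permuted, 1 of 100 gave as many genes as the real 876 by limma (highest other 12). As this breaks the female pairs, it does not exclude chance either. For the interaction lists the permutation gave 1 of 100 (17 against up to 16). By the splits chance was not excluded for the lists called in males (10 of 35 splits, 15 lists against up to 19), in females (3 of 60, 18 against up to 19) or for the interaction (5 of 60, 17 against up to 19), since lists of correlated genes are called in many splits.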
